A study of Homo sapiens with 6 samples.

How the data were processed

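Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in RKO, an established human colon carcinoma cell line grown without treatment. The series has 6 samples, 1 for each of ING2, ING5, Brpf2, H3K4me3, histone H3 and rabbit IgG, grouped by the immunoprecipitated target in the labels. The processed peak list of the Brpf2 sample was the material used, and the other 5 samples were not analysed here. Brpf2, also called BRD1, is a bromodomain and PHD-finger scaffold subunit of MYST acetyltransferase complexes. With 1 library and no replicate, no test between samples was made. Intervals and p-values below therefore describe how peaks are distributed within this library, and peaks are not independent replicates.

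The deposited list gives for each peak its chromosome, start, end, name and a score in hg18 coordinates. BWA, SAMtools, bedtools and the build hg18 are named in the submitters' processing notes, without versions or roles. The peak names in the file carry the name of the caller MACS. Its version, settings and control library are not given in the sources used here. The score in the deposited file is the value the authors' caller gave to each peak. Its scale is not stated in the file. The lowest score, 50, is what log10 of a p-value of 1e-05 gives after multiplication by minus 10, and the highest, 3233.06, is what the smallest positive number in double precision gives on that scale. This reading is an inference from the values, and the score was used only within the list, to rank and filter peaks and to compare medians between groups of peaks. The number of reads behind the peaks is not in the list, so the depth is unknown and no value per peak has a counting interval.

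Peak positions were used as listed, including 2 peaks whose starts lie before position 1 (on chromosomes 9 and 16), and are given here counted from 1. No peaks overlapped. No lengths or gene positions of hg18 were used. Chromosome length was taken as the end of the last peak on that chromosome, which departs from the plan to use reference lengths. The numbers of genes per chromosome came from the RefSeq table of GRCh38.p14, from which only the chromosome and type of each gene were taken, because positions of different builds cannot be combined. It placed 20037 protein-coding genes on the 24 chromosomes. Peaks were therefore not assigned to genes. The planned tests of promoters, of gene lists at promoters and of sequence composition were not run. Of the planned gene lists, the olfactory receptor genes alone were used, through their chromosomes.

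Peak counts per chromosome were compared with length by a chi-square statistic whose p came from 100000 multinomial draws. Ratios of observed to expected peaks have exact Poisson 95% intervals, and shares have exact Clopper-Pearson 95% intervals. For a share of 0 the text gives the share that 3 counts would make, and the plotted interval is the exact one. These cover counting error only. Densities of peaks and genes were correlated over 23 chromosomes (Y left out) with 100000 permutations, two-sided, and Benjamini-Hochberg adjustment over 7 gene classes. Clustering was the share of peaks with a neighbour within 10 kb, edge to edge, against 1000 random placements of the same widths between the first and last peak of the same chromosome (one-sided). Score and width were related by Spearman's rho with 100000 permutations. Medians per chromosome have bootstrap 95% intervals from 2000 draws. The rule for named regions was fixed before the data were examined: the 10 highest scores (ties broken by width), the 5 widest peaks, the 5 windows of 1 Mb with the most peaks on a grid from position 1, and the longest stretch between neighbouring peaks. Peaks were placed in windows by their midpoints.

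The alternatives fixed in advance were the peaks at or above the median score, joining of peaks within 1 kb, autosomes alone, all annotated genes, and neighbour distances of 2 kb and 50 kb. Others were added after seeing the data: peaks at or above or below a score of 3100, the span from the first to the last peak as length, leaving out the 2 chromosomes of most extreme gene density, and placement within the same window of 1 Mb, also with peaks within 1 kb, 2 kb or 10 kb joined. The joined peaks were first compared with regions left as placed. After those results were seen, a second comparison was added in which the placed regions were joined in the same way. The rule for the verdict on splitting was changed after results were seen, and then again. It first used the first comparison alone, which gave that splitting fits, then the second alone, which gave that it does not, and now asks that both agree, which they do not. The code was tested on simulated data. With all 11874 peaks placed at random, the clustering test called 2 of 20 simulated lists at p of 0.05 or less. With 1000 peaks planted near a neighbour, 25.0% of peaks had a neighbour within 10 kb, against 11.6% under random placement. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.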

Results

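Brpf2 occupancy was mapped genome-wide in untreated RKO cells, in a series that also targeted ING2, ING5 and the promoter-associated histone mark H3K4me3. The Brpf2 peak list of 1 library was analysed, and comparisons with the ING2, ING5, H3K4me3, H3 and IgG libraries were not made here.

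The list held 11874 Brpf2 peaks on 24 chromosomes, which together covered 30.7 Mb. The median peak was 2333 bp wide (bootstrap 95% interval 2308 to 2354 bp), and the quartiles were 1718 and 3092 bp. The narrowest peak spanned 438 bp and the widest 54699 bp. Peaks narrower than 2 kb made up 36.3% of the list, and 540 peaks were 5 kb or wider. Of these, 41 reached 10 kb. The median distance between neighbouring peaks was 70.1 kb, with quartiles of 24 and 193 kb.

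The caller's score, which is the authors' own value for each peak, ranged from 50 to 3233.06 with a median of 614. Scores piled up at 3100, where 921 peaks had exactly this value and 23 peaks lay in the 50 units just below it. A further 61 peaks scored above 3100. In all 982 peaks, or 8.27% of the list, stood at or above 3100, called the ceiling here although it is not the highest score. If the score is a capped p-value, it cannot order these 982 peaks by strength. The 61 peaks above 3100 then need not be stronger than the 921 at exactly 3100.

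The 10 peaks with the highest scores lay on 9 different chromosomes and were between 2441 and 6836 bp wide. These 10 peaks rank highest by score only and need not be the strongest, since many other peaks had a score of exactly 3100. A score of 3233.06 was shared by 5 of them. The widest of these 5 was on chromosome 8 from 145483063 to 145489898, with 5 other peaks within 100 kb. Of the others, 2 were on chromosome 3, from 33453950 to 33458519 and from 108723828 to 108728288. The remaining ones were on chromosome 17 from 78069941 to 78073754 and on chromosome 1 from 28935391 to 28939023. The next 5 by score were on chromosome 7 from 23534425 to 23538803 (3230.05), chromosome 15 from 78773742 to 78776980 (3225.28) and chromosome 10 from 97792591 to 97795420 (3224.03), followed by chromosome 16 from 66152958 to 66156386 (3217.15) and chromosome 2 from 223433492 to 223435932 (3214.74). The peaks on chromosome 3 from 33453950, on chromosome 15 and on chromosome 2 had no other peak within 100 kb. All positions are in hg18, and no gene annotation of that build was used, so the genes at these sites are not named.

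Wide Brpf2 peaks were mostly high-scoring ones. Across the 11874 peaks, score and width rose together (Spearman's rho = 0.80, permutation p = 1e-05, the smallest these permutations can give). Both values come from the same caller and the same library, so a relation between them may be built in. It shows that the score cannot be read apart from width, and it is not evidence of a property of Brpf2. Of the 499 peaks between 5 and 10 kb wide, 72.9% (exact 95% interval 68.8 to 76.8%) were at or above 3100, and 35 of the 41 peaks of 10 kb or more were too. Among peaks of 3 to 5 kb the share was 19.6% (18.1 to 21.1%), and among those of 2 to 3 kb it was 1.29% (0.979 to 1.68%). It was 0 of 4311 among narrower peaks, which allows a share of up to 0.0696% by a limit of 3 counts. Peaks at the ceiling had a median width of 4580 bp, against 2224 bp for the rest. Restricting the relation to peaks at or above the median score gave a rho of 0.62.

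**Figure D1:**
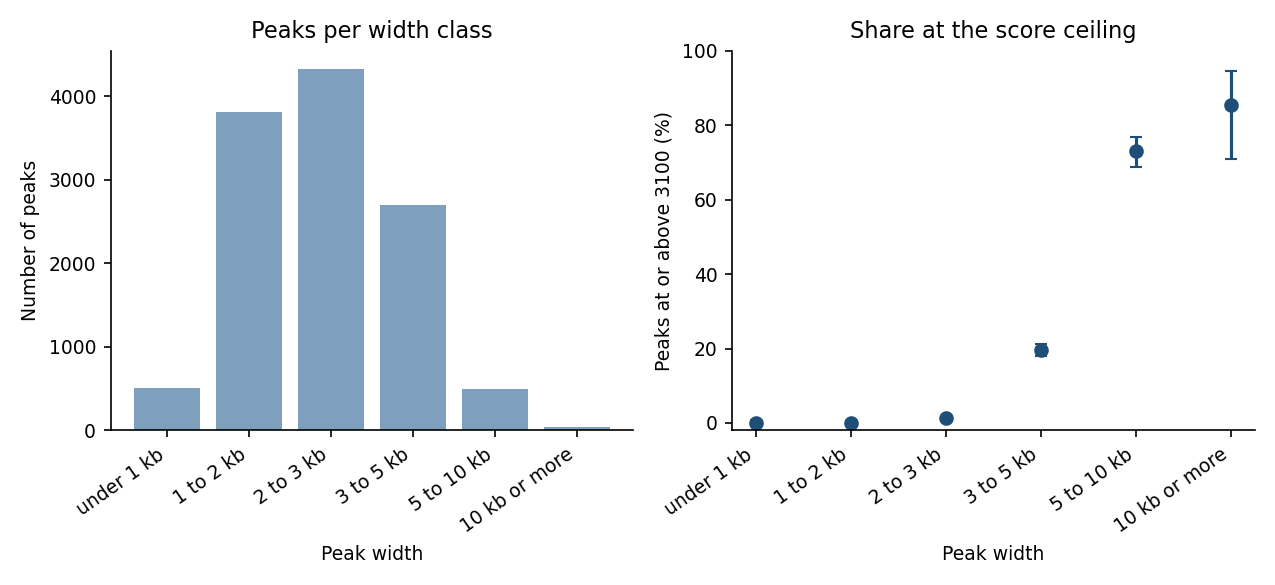
Left, bars give the number of Brpf2 peaks in each width class. Right, points give the percentage of peaks in each class with a score of 3100 or more, with exact 95% binomial intervals. The share rises from 0 below 2 kb to 72.9% at 5 to 10 kb.

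The 5 widest peaks included 3 with a score of exactly 3100. These lay on chromosome 5 from 141670225 to 141689199 (19 kb), on chromosome X from 45501624 to 45519534 (17.9 kb) and on chromosome 17 from 60075450 to 60091904 (16.5 kb). The widest of all, on chromosome 7 from 130229276 to 130283974 (54.7 kb), scored 993.66. The next widest, on chromosome 8 from 145703293 to 145725964 (22.7 kb), scored 135.54, below the lower quartile of all peaks (233.9).

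Brpf2 peaks were spread unevenly over the chromosomes relative to their lengths. Chromosome 19 carried 818 peaks, 3.32 times the number for its length (95% interval 3.10 to 3.56), and chromosome 17 carried 741, a ratio of 2.44 (2.27 to 2.62). Chromosomes 16 and 22 followed with ratios of 1.61 (1.48 to 1.75) and 1.54 (1.37 to 1.72). With the end of the last peak as length, the lowest ratios among autosomes were 0.49 on chromosome 13 (0.43 to 0.56), 0.57 on chromosome 4 (0.51 to 0.62) and 0.57 on chromosome 18 (0.49 to 0.66). With the span from the first to the last peak as length, chromosome 13 had 0.566 and chromosome 18 had 0.553, so their order depended on the length used. Chromosome X had 350 peaks and a ratio of 0.59 (0.53 to 0.65). Chromosome Y had 11 peaks, none of them at the score ceiling. They lay between 132740 and 2620945, except those that start at 10644721, 19613765 and 57758099. Which of them lie in sequence shared with chromosome X was not examined, so they cannot all be counted as specific to chromosome Y. With the end of the last peak as length, the interval lay above 1 for 8 chromosomes and below 1 for 10. The counts departed from those by length (chi-square = 3060, 23 degrees of freedom, p = 1e-05 from multinomial draws, the smallest these draws can give). Neighbouring peaks are not independent, so this p and the intervals are too narrow.

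**Figure D2:**
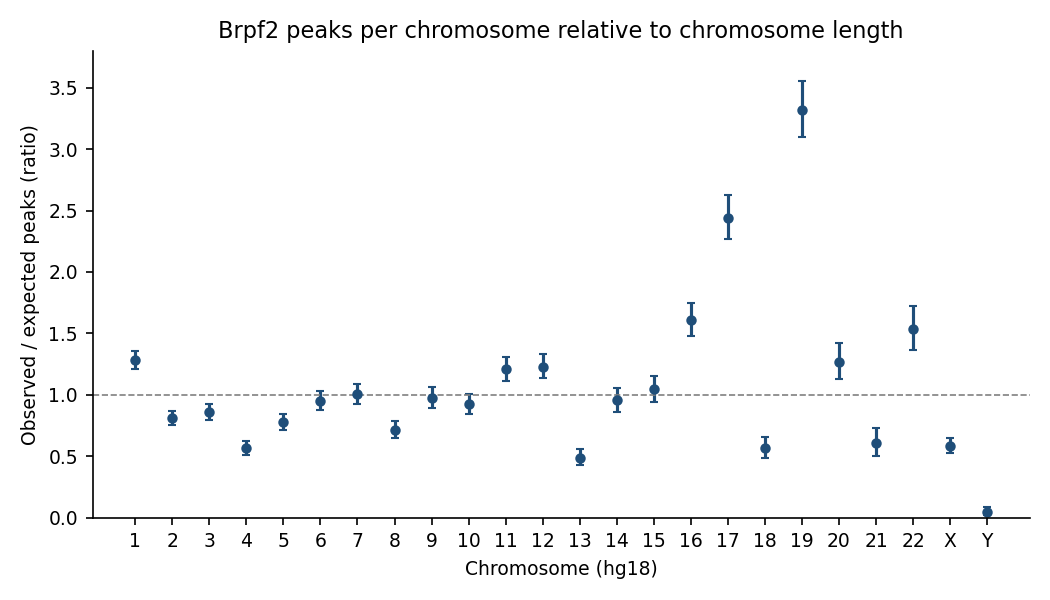
Each point is the number of Brpf2 peaks on a chromosome divided by the number its length would give (dashed line, ratio of 1), with exact Poisson 95% intervals. Length is the end of the last peak. Chromosome 19 stands at 3.32 and chromosome 17 at 2.44, while chromosomes 4, 13, 18, X and Y lie below 0.6.

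The chromosomes that held many Brpf2 peaks were those that hold many protein-coding genes. Chromosome 19 had 12.8 peaks and 22.8 protein-coding genes per Mb, chromosome 17 had 9.42 and 14.9, chromosome 18 had 2.19 and 3.55, and chromosome 13 had 1.89 and 2.96. Over 23 chromosomes, the density of peaks followed that of protein-coding genes with Pearson's r = 0.98 and Spearman's rho = 0.95 (permutation p = 1e-05 for each, the smallest possible, and adjusted p = 1.7e-05 and 3.5e-05 over 7 gene classes). Without chromosomes 17 and 19, which lie farthest from the median gene density, r was 0.93 (permutation p = 1e-05). With peaks at or above 3100 alone it was 0.89. Both densities were divided by the same lengths, which by itself gave a median r of 0.26 when gene counts were permuted across chromosomes. Chromosomes are not replicates of the experiment, and the gene counts come from GRCh38.p14.

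Set against protein-coding genes, the list held 59.3 peaks per 100 genes. Autosomes ranged from 46.0 on chromosome 21 (95% interval 37.8 to 55.5) to 67.5 on chromosome 9 (61.8 to 73.5). Chromosome 19 had 56.4 (52.6 to 60.4), chromosome 17 had 63.4 (58.9 to 68.1), chromosome 13 had 63.9 (55.7 to 73.0) and chromosome 18 had 61.9 (52.8 to 72.0). Chromosomes 11, 21, X and Y had intervals below the overall value, with 48.0 peaks per 100 genes on chromosome 11 and 41.3 on chromosome X. Chromosomes 7, 9, 10 and 15 had intervals above it. The spread among chromosomes was still larger than counting error (chi-square = 148, 23 degrees of freedom, p = 1e-05 from multinomial draws, the smallest possible), but far below the chi-square of 3060 against length.

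**Figure D3:**
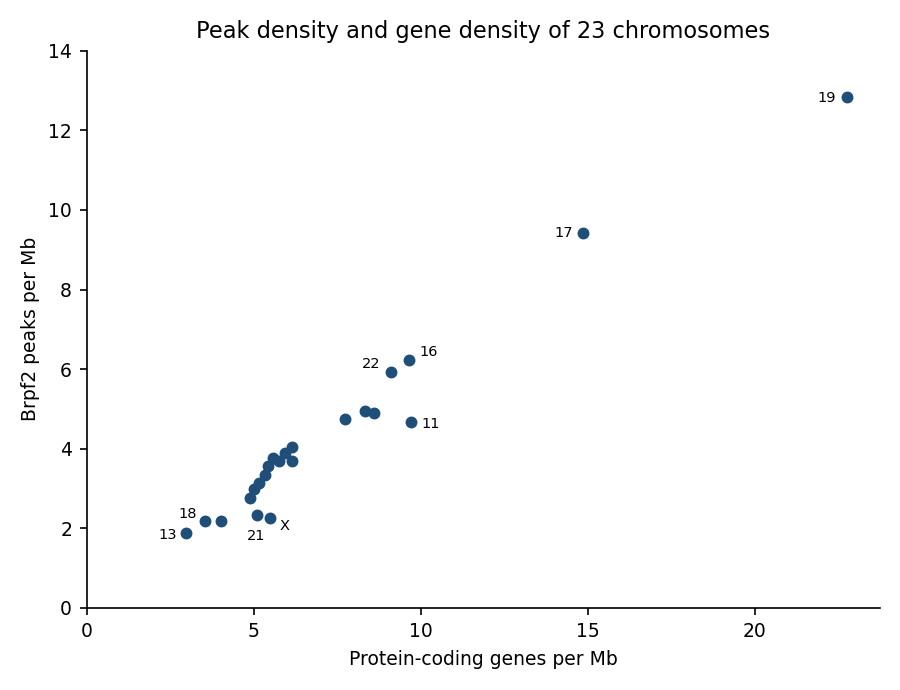
Each point is 1 of 23 chromosomes (Y left out), with protein-coding genes per Mb on the horizontal axis and Brpf2 peaks per Mb on the vertical axis, and some points labelled. The points rise together (r = 0.98), with chromosome 19 at 22.8 genes and 12.8 peaks per Mb and chromosomes 11, 21 and X below the general trend.

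Along chromosomes, the density of Brpf2 peaks varied widely. Of 3003 windows of 1 Mb between the first and last peaks, 874 (29.1%) held no peak, where a Poisson distribution with the same mean of 3.95 would leave 1.92% empty. Windows that cannot be aligned to were not left out, and the Poisson share uses 1 mean for chromosomes that differ in density, so it is a rough reference. At the other end, 70 windows held 20 or more peaks. They were 2.33% of the windows and held 14.5% of the peaks, and 15 of them were on chromosome 19, 8 on chromosome 16 and 8 on chromosome 17. The most crowded window, on chromosome 19 from 1000001 to 2000000, held 39 peaks that covered 117 kb, 8 of them at or above 3100. It was followed by chromosome 16 from 30000001 to 31000000 with 38 peaks, none at the ceiling and with a median score of 424. Chromosome 17 from 7000001 to 8000000 held 36 peaks, chromosome 19 from 12000001 to 13000000 held 35, and chromosome 16 from 2000001 to 3000000 held 34.

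The longest stretch between neighbouring peaks was 38.1 Mb on chromosome Y, from 19614545 to 57758098. On the other chromosomes it was 21.8 Mb on chromosome 1, from 120728023 to 142533658, a stretch named after its length was seen. Which parts of these stretches can be aligned to was not examined.

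**Figure D4:**
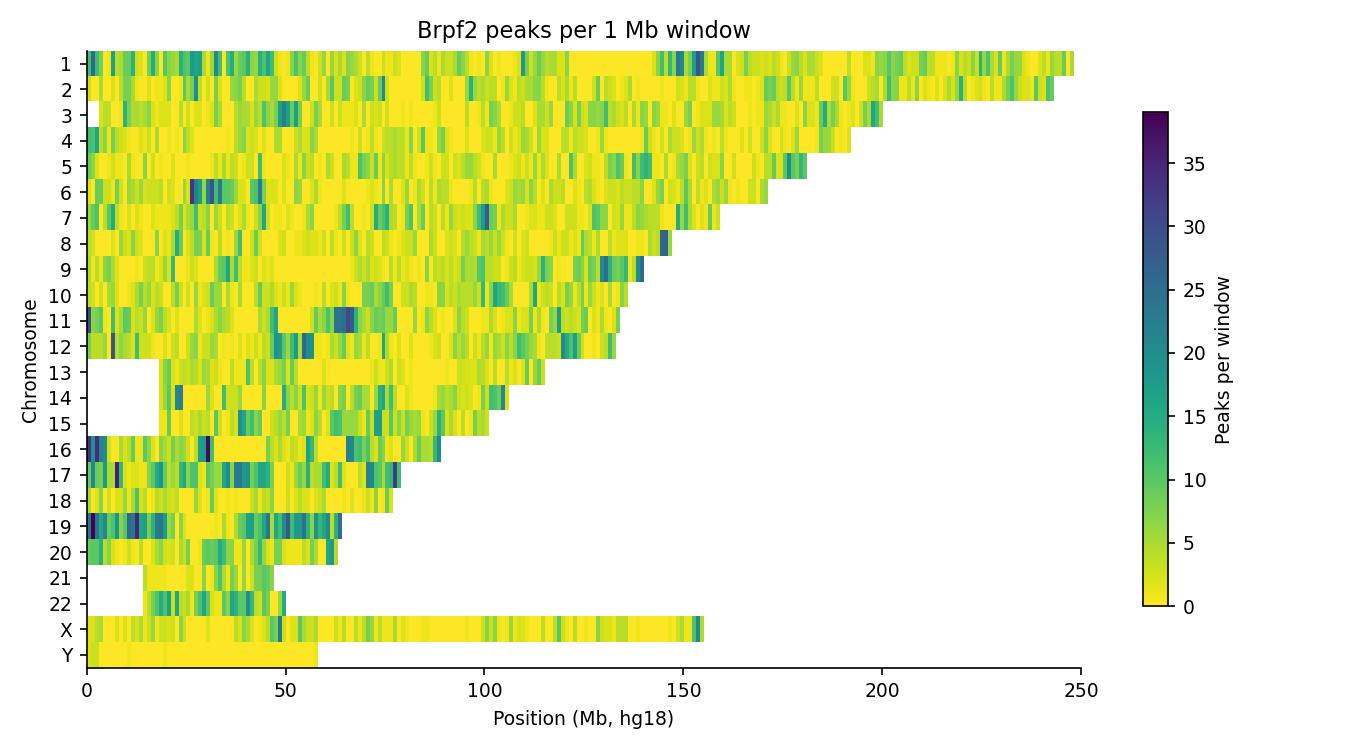
Rows are chromosomes and each cell is a window of 1 Mb in hg18, coloured by its number of Brpf2 peaks, with white outside the first and last peak. Dark cells are concentrated on chromosomes 16, 17 and 19, and the darkest holds 39 peaks.

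Brpf2 peaks also lay close to each other more often than random placement gave. A neighbour within 10 kb was found for 2727 peaks, or 23%, against a mean of 11.6% (95% of placements between 10.8 and 12.4%), which is 1.98 times as many (one-sided permutation p = 0.001 from random placement, the smallest that 1000 placements can give). Within 2 kb the shares were 8.35% and 4.42%, and within 50 kb they were 60.0% and 38.7%. Placements could also fall in stretches that cannot be aligned to, which would lower the random shares and raise the ratios. The excess of close peaks was smaller when density on the larger scale was kept. When peaks were moved only within their own window of 1 Mb, 20.1% had a neighbour within 10 kb and the ratio was 1.14 (one-sided permutation p = 0.001). In both kinds of placement moved peaks could overlap and then counted as close, whereas listed peaks do not overlap. This raises the random shares and lowers the ratios by an amount not measured. How much of the excess goes with density is therefore not settled. The excess left within windows depended on the treatment of close peaks. With peaks within 1 kb joined first, the ratio was 0.91 against moved regions left as they fell, and 1.25 against moved regions joined in the same way, a comparison added after the first value was seen. With placement anywhere on the chromosome, joining lowered the ratio from 1.98 to 1.58.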

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

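The correlations and the chi-square tests stayed past their thresholds under each alternative that was run for them, and the clustering ratio stayed above 1 except in 2 of the settings chosen after seeing the data. Of the 28 alternatives to the main results, 23 kept the direction and side of the threshold or, for the number of peaks, stayed within 1.5 times the main count (11481 after joining peaks within 1 kb). Of the other 5, 3 followed from the construction of the subset: the peaks at or above the median score numbered 5937 and had a median width of 2989 bp, and joining peaks within 1 kb raised the median width to 2382 bp. The correlation of peak with gene density ranged from 0.89 (peaks at or above 3100) to 0.99 (autosomes), and that of score with width from 0.62 (peaks at or above the median score) to 0.79 (autosomes). The clustering ratio, 1.98 as reported, was 1.89 within 2 kb, 1.55 within 50 kb, 1.72 among peaks at or above the median score, 1.58 with peaks within 1 kb joined, and 1.14 with placement within the same window of 1 Mb. With that placement and peaks joined first it was reversed, to 0.91 (joined within 1 kb) and 0.83 (joined within 2 kb). With the placed regions joined in the same way, a comparison added after those 2 values were seen, it was 1.25 and 1.28. Neither comparison is neutral. In the first, placed regions can lie within the joining distance and joined peaks cannot, which lowers the ratio. In the second, regions already joined are joined again, which raises it: a list of peaks placed at random on whole chromosomes gave 1.06, and this was not measured within windows. Of 20 alternative ratios for chromosomes 13, 17, 18 and 19, none crossed 1 and 5 lay outside the counting interval of the main value. For chromosome 19 these were 2.53 among peaks at or above the median score and 2.75 among those at or above 3100. For chromosome 17 it was 1.99 among peaks at or above 3100. For chromosome 13 they were 0.566 with the span from the first to the last peak as length and 0.631 among peaks at or above 3100. Chromosome 18 was lower than chromosome 13 in both settings, with 0.553 and 0.494. The causes were not tested. The alternatives for promoters, gene lists and sequence composition were not run, since no annotation or sequence of hg18 was used. The read depth is unknown, so how many further weak peaks a deeper library would give cannot be estimated.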

Other observations

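The tests on peak width along chromosomes were chosen after their pattern was seen. The comparisons of scores between chromosomes and of other gene classes, and the tests with placement within the same window of 1 Mb, were added to the plan after the data were in hand. For joined regions within such windows, 2 comparisons were tried, the second and the rule that both must agree after earlier results were seen. The tests of shared chromosome lengths for protein-coding genes, copy number, olfactory receptor genes, regions joined within 10 kb against placement anywhere on the chromosome, and close pairs were set before their results were seen.

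Brpf2 peaks on chromosome X were fewer per gene, lower in score and narrower than those on the autosomes. There were 41.3 peaks per 100 protein-coding genes on X and 60.2 on the autosomes. The median score was 281 for the 350 peaks on X and 630 for the 11513 on autosomes (difference −348, permutation p = 0.0001, the smallest that 10000 permutations can give). The median width was 1682 bp against 2352 bp (permutation p = 0.0001), and 2.29% against 8.46% of peaks were at or above 3100. On chromosome 19, where peaks were densest, the median score was 403 (bootstrap 95% interval 362 to 440). Chromosome 8 had the highest median score, 852 (719 to 1016). The range of chromosome medians, 571, exceeded that of shuffled scores, whose median was 201 (permutation p = 0.001, the smallest that 1000 shuffles can give).

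For other gene classes, Pearson's r with the density of Brpf2 peaks over the 23 chromosomes ranged from 0.24 to 0.93. Each class was tested one-sided against gene counts permuted across chromosomes with the lengths kept. The shared lengths are thus part of chance, and adjustment was over 7 classes. Pearson's r was 0.93 for miRNA genes (adjusted permutation p = 2.3e-05), 0.88 for pseudogenes (adjusted permutation p = 3.5e-05) and 0.66 for lncRNA genes (adjusted permutation p = 0.036), where chance gave a median r of 0.28 for lncRNA genes and 0.61 at its 95th percentile. It was 0.27 for snoRNA genes (adjusted permutation p = 0.45), close to the median of 0.24 that chance gave, and 0.24 for tRNA genes (adjusted permutation p = 0.22). Spearman's rho passed for these classes too, with 0.63 for snoRNA genes (adjusted permutation p = 0.0024) and 0.45 for tRNA genes (adjusted permutation p = 0.034), so their relation depends on the measure used. Spearman's rho was 0.75 for miRNA genes, 0.81 for pseudogenes and 0.72 for lncRNA genes (adjusted permutation p = 5.6e-05, 2.3e-05 and 5.6e-05). Without the 2 chromosomes farthest from each class's median density, r was 0.67 for miRNA genes, 0.72 for pseudogenes, 0.65 for lncRNA genes, 0.65 for snoRNA genes and 0.32 for tRNA genes, values that were not tested with the lengths kept. The differences between classes were not tested.

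The match between peak and protein-coding gene density was larger than shared chromosome lengths give. With gene counts permuted across chromosomes and lengths kept, no permutation reached the observed r (p = 1e-05, the smallest possible), and 95% of them gave r below 0.61. Genes of the olfactory receptor family, which are silent in most tissues, may account for part of the remaining scatter. Leaving 392 of them out raised r by 0.0032, where leaving out as many random genes changed it by −0.00072 to 0.00063 in the middle 90% of draws, and chromosome 11, which holds 171 of them, went from 48.0 to 55.3 peaks per 100 genes. The random genes were not matched for chromosome, so the rise may come from where these genes lie. No peak was assigned to a gene, so how many peaks they carry is not known. Chromosome copy number as a source of the differences in peaks per gene cannot be told apart from other sources: median score and peaks per gene gave a rho of 0.0069 over 23 chromosomes, with a bootstrap interval of −0.47 to 0.49. Chromosome X was the lowest of the 23 in both measures.

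How far splitting of broad regions by the caller made the grouping of peaks within windows of 1 Mb cannot be told. The ratio there was 1.14 with peaks as listed. After peaks within 1 kb were joined it was 0.91 against regions left as placed, which would fit splitting. Against regions joined in the same way, tried after that value was seen, it was 1.25, which would not. The first comparison leans to low ratios and the second to high ones, so the sign for peaks joined within 1 kb depends on this choice. After peaks within 10 kb were joined into 10328 regions, 50.1% had a neighbour within 50 kb, 1.44 times the share under placement anywhere on the chromosome. That value passed the limit set in advance against splitting, but density on the scale of 1 Mb would raise it as well. Within windows of 1 Mb the ratio for these regions was 1.03 against regions left as placed and 1.29 against joined ones (one-sided permutation p = 0.003 and 0.001). Both were above 1, the first only slightly. The closest pairs may in part be a strong peak with a weak flank called apart: in the 526 pairs within 2 kb the median of the lower score was 115, against 249 to 327 in 95% of shuffles within chromosomes, and the members' scores ran in opposite directions (rho = −0.25, permutation p = 0.001). The median of the higher score, 914, was also below that of shuffled pairs (1052 to 1309), so the pairs as a whole scored low and the reading stays open.

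On parts of chromosomes 8, 9 and 20, Brpf2 peaks were wide for their score. After matching on score in 20 bins, 5 of 151 segments of 20 Mb exceeded a median log2 width shift of 0.27, the level that the highest segment passed in 5% of shuffles. These were chromosome 8 from 100 Mb on (3 segments), chromosome 9 from 120 to 140 Mb and the segment of chromosome 20 that starts at 60 Mb. The last segments of chromosomes 8 and 20 are shorter, since the last peaks end at 146 and 62.4 Mb. In the other direction, 3 segments passed the matching limit of −0.24: chromosome X from 0 to 20 Mb and from 120 to 140 Mb (−0.28 each) and chromosome 6 from 60 to 80 Mb (−0.33). The 388 peaks of the wide segments had a log2 shift of 0.47, measured in the peaks that picked the segments. When segments were picked on every other peak and measured in the rest, chromosome 9 from 120 to 140 Mb and chromosome 8 from 140 Mb on were picked both times, once with chromosome 8 from 120 to 140 Mb, and the shifts were 0.51 (bootstrap 95% interval 0.42 to 0.60) and 0.55 (0.44 to 0.69). The segments of chromosome 20 and of chromosome 8 from 100 to 120 Mb were not picked in this way. Neither crowding nor closeness to the chromosome end gave shifts of this size elsewhere: windows of 20 or more peaks on the other chromosomes shifted by 0.093 (0.076 to 0.111), and the last 20 Mb of 21 other chromosomes by 0.015 (0.00027 to 0.038). Extra copies of these segments in the cell line are a candidate explanation that stays open, as does a wider spread of Brpf2 there. The lower quartile of width was shifted by 0.44 in the 5 segments, and by 0.53 and 0.46 in the peaks left over from picking. The pooled median score was 1060 against 686 on the rest of the same chromosomes. On chromosome 8 the score did not single out the wide segments, whose median scores were 1166, 951 and 1064. Its segments from 40 to 60 Mb and from 60 to 80 Mb had 1379 and 1267, with width shifts of 0.014 and 0.099. Those from 0 to 40 Mb and from 80 to 100 Mb scored lower (548, 625 and 813). No coverage or copy-number data were used.

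Of the 50 widest peaks, 43 had a score of 3100 or more and 7 did not, the widest 2 among the latter.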
